A study of Mus musculus with 12 samples.

How the data were processed

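mRNA of 12 libraries from stable J1 mouse embryonic stem cell lines was profiled, 2 libraries in each of 6 groups. Per the labels' protocols, total RNA was extracted with Trizol, mRNA was captured, and libraries were sequenced on a HiSeq X-10. The labels name both the NEBNext Ultra and the TruSeq v2 library kits, and which kit made which library is not given in the sources used here. Cells grew on fibroblast feeders, and no step that removed feeder cells before RNA extraction is given in the sources used here.

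The deposited values are FPKM per gene symbol, made by the authors, with 1 value column in each of 12 files. The unit is inferred from the values themselves, which change in steps set by depth and transcript length. The submitters' processing notes name TopHat2 2.0.13, Cuffdiff 2.2.1 and the mm10 genome build, while the role of each tool, its settings and the gene annotation are not given in the sources used here. Cuffdiff can scale libraries to each other before it reports FPKM, and whether that was done within each arm or over both is not known. Each file lists 23355 genes, of which 23354 are shared by all 12. The symbol sets of the arms differ by 2 genes, Nolc1 and Inpp5d, which were not analysed here. FPKM splits reads between transcripts and copies of a gene by model, and values near 0 rest on few fragments.

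Depth was recovered from the steps between low values. In 602 low genes with a single annotated transcript, 94.91% of 2025 values were whole steps within a tolerance of 0.05, where chance gives 10%. This puts 1 FPKM of a 2 kb transcript at 44.7 to 59.0 fragments. The estimate is approximate, since it assumes full transcript lengths.

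The files hold no read counts, so the test was limma (version 3.58.1 in R 4.3.3) on log2(FPKM + 1), with values used as deposited. Fold changes on this scale understate the change of low genes, and folds printed as such are ratios of mean FPKM. Genes with at least 1 FPKM in at least 2 libraries were kept, which left 13109. A single fit over all 12 libraries had a mean for each of 6 groups, 6 residual degrees of freedom and a prior of 3.66 from the intensity trend, so that all groups shared an estimate of the spread. That estimate is an average, so p-values can be too small for groups that vary more, such as H3.1K9M, and too large for groups that vary less. No replicate block was used. p-values are two-sided, adjusted by the Benjamini-Hochberg method over the tested genes of a comparison, with a threshold of 0.05 for calling a gene. The 6 main contrasts answer the design's questions, and the control lines were compared as background.

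Gene lists were tested with camera, which compares the genes of a list with all other tested genes, at a preset correlation of 0.01 between genes. Of 38 lists, 37 had at least 5 tested genes. Adjusted p-values are over the lists of a comparison. Camera with an estimated correlation and fry, a rotation test of whether the genes of a list move one way on balance, were run beside it, and members were also adjusted over the list alone.

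The tests, the lists, the rule for naming genes and most alternatives were fixed before the data were examined. Which lists are described, and the patterns and tests under the other observations, were chosen after seeing the data. So were 3 further alternatives: the feeder marker mean as a covariate, genes on chromosomes 11, 16, 19 and Y left out, and H3.1K9M replicate 1 left out everywhere. The rule named Suv39h1 and Suv39h2 throughout, and up to 10 rising and 10 falling genes per comparison with the largest fold changes. These had to pass the test, have libraries that did not overlap between the groups and reach 3 FPKM in the higher group, and predicted, unnamed and small RNA genes were skipped. From each described list it named up to 4 members with the smallest p, whether they passed or not, and up to 10 genes called in both of a pair of H3K9 responses. Alternatives fixed beforehand were a pseudocount of 0.1, no filter or a filter of 5 FPKM, quantile or median-of-ratios scaling, array quality weights, a replicate block, fits over fewer groups, a threshold on the fold change and leaving out each library.

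The steps were tested on simulated data made from each gene's mean over all 12 libraries. Every library was given the same spread per gene, averaged over the 6 groups. The wider spread of H3.1K9M, with an SD of 0.41 between its libraries, was not reproduced, so the numbers for it may be too favourable. For H3.1K36M against H3.1WT, 92 of 100 genes planted with a log2 change of 1 were recovered among 12818 genes, and 100 of 100 at a change of 2. For H3.1K9M the numbers were 91 and 97 among 12838 genes, for shSuv39h1 93 and 98 among 12830, and for shSuv39h2 90 and 100 among 12828, with planted genes at a mean log2 level of at least 2.5. Calls among genes with nothing planted numbered 19 in H3.1K36M, 19 in H3.1K9M, 5 in shSuv39h1 and 10 in shSuv39h2. Gene positions were taken from GENCODE M21 on GRCm38, matched by symbol for 12344 tested genes, or 94.2%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.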

Results

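mRNA was measured in stable lines of J1 mouse embryonic stem cells, a male line, grown on mouse embryonic fibroblast feeder cells with serum and leukemia inhibitory factor. The 12 libraries formed 6 groups of 2. In the overexpression arm the cells carried wild-type histone H3.1 (H3.1WT, the control), H3.1K9M or H3.1K36M, in which lysine 9 or lysine 36 is replaced by methionine. Such lysine-to-methionine histones are known to lower methylation of that residue on the histone pool around them. In the knockdown arm the cells carried a hairpin against Suv39h1 or Suv39h2, which encode a pair of H3K9 methyltransferases of heterochromatin, or the hairpin shNC, read as the non-targeting control. The series title concerns H3K36me3 and single nucleotide variation, and the comparisons below ask which transcripts differed when either mark was targeted. Depth was approximated from the values, and 1 FPKM of a 2 kb transcript stood for 44.7 to 59.0 fragments. Between 12126 and 12518 genes per library reached 1 FPKM. Across genes, the SD of the log2 difference between the libraries of a group was 0.41 in H3.1K9M, 0.345 in shNC and 0.26 in H3.1WT, and it lay between 0.223 and 0.235 in the other groups. Levels are given as mean FPKM ± SD with n = 2. The labels do not say whether the libraries of a group were separate cultures, so p-values measure the spread between these libraries, which may be technical.

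Suv39h1 (GRCm38 chromosome X, 8061171 to 8074760) averaged 5.01 ± 0.136 FPKM (SD, n = 2) in shSuv39h1 and 8.05 ± 0.743 in shNC, 62.2% of control. The limma log2 fold change of −0.59 (SE 0.105) did not pass the test, with an adjusted p of 0.0877. Individual libraries stood at 4.91 and 5.10 FPKM in shSuv39h1 against 8.58 and 7.52 in shNC. Suv39h2 (chromosome 2, 3455815 to 3475031) fell from 4.79 ± 0.0106 in shNC to 1.68 ± 0.104 FPKM in shSuv39h2, 35.1% of control, with a limma adjusted p of 0.000304. The shSuv39h2 libraries were at 1.61 and 1.76 FPKM and the shNC libraries at 4.797 and 4.782. Suv39h1 stood at 10.1 ± 0.544 FPKM in shSuv39h2, 126% of control, a difference that did not pass (adjusted p = 0.105). Suv39h2 stood at 5.02 ± 0.229 in shSuv39h1, 105% of control (adjusted p = 0.884). In the overexpression arm Suv39h1 was at 11.3 ± 1.38 FPKM in H3.1WT, 11.1 ± 0.119 in H3.1K9M and 7.25 ± 0.467 in H3.1K36M, where it fell to 64.4% of control (adjusted p = 0.0163). Suv39h2 was at 5.53 ± 0.145, 6.05 ± 0.58 and 5.47 ± 0.159 FPKM in the same order. The overexpressed histones could not be checked in this way. Across 12 replication-dependent H3 genes the highest value was 15.9 FPKM in the overexpression libraries and 20.5 FPKM in the knockdown libraries.

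**Figure D1:**
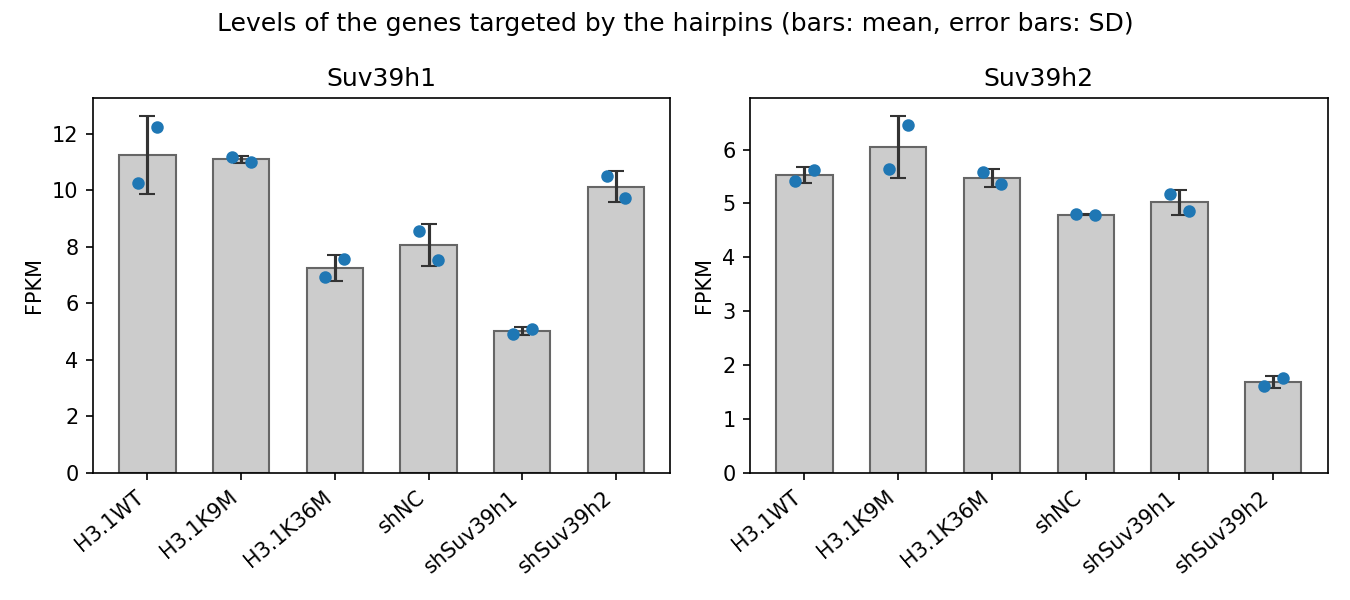
FPKM of Suv39h1 (left) and Suv39h2 (right) in the 6 groups, with bars for the mean, error bars for the SD and points for the 2 libraries of each group. Suv39h1 averaged 5.01 in shSuv39h1 and 8.05 in shNC, and Suv39h2 averaged 1.68 in shSuv39h2 and 4.79 in shNC.

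H3.1K9M was compared with H3.1WT to ask which transcripts differed when methylation of H3K9, a mark of silent chromatin, was targeted. Of the 41 genes that passed 38 fell, among them 5 of the 2-cell-like list, 2 of the list of germline genes silenced by promoter DNA methylation and 2 of the X-linked Rhox, Xlr and Mage list, and 6 lay on chromosome X. Zscan4d, a zinc finger gene expressed transiently in the 2-cell embryo, fell from 5.42 ± 0.932 to 1.05 ± 0.302 FPKM (SD, n = 2), a 5.17-fold decrease (limma adjusted p = 0.0178). Its neighbours Zscan4f, Zscan4c and Zscan4e fell 2.65-fold, 2.87-fold and 3.92-fold. Dazl, a germ cell RNA-binding protein, fell from 4.31 ± 0.652 to 1.503 ± 0.174 FPKM (adjusted p = 0.0227). Gadd45a, a gene induced by DNA damage and other stress, rose from 17.2 ± 1.05 to 27.6 ± 0.633 FPKM (adjusted p = 0.0365).

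Of 17 tested members of the 2-cell-like list, 5 fell and none rose in H3.1K9M, and adjusted over the list alone 13 fell. The list's median log2 fold change was −0.77 (camera adjusted p = 1.5e-16; adjusted p = 0.139 with an estimated correlation). Among 19 X-linked Rhox, Xlr and Mage genes, families expressed mainly in germ cells and placenta, 2 fell, and adjusted over the list alone 12 fell. Their median was −0.43 (adjusted p = 2.62e-11; adjusted p = 0.105 with an estimated correlation). Xlr3b fell from 11.2 ± 1.87 to 4.54 ± 1.11 FPKM and the homeobox gene Rhox13 from 4.87 ± 0.348 to 1.99 ± 0.741, while Rhox10 (2.89 against 7.49 FPKM, adjusted p = 0.0691) and Mageb4 (0.721 against 1.90 FPKM, adjusted p = 0.0939) did not pass. In the list of germline genes silenced by promoter DNA methylation, 2 of 26 fell, and adjusted over the list alone 11 fell, with a median of −0.41 (adjusted p = 9.86e-11; adjusted p = 0.139 with an estimated correlation). Those genes were Dazl and Syce1, a synaptonemal complex gene, which fell from 19 ± 1.52 to 10.6 ± 1.87 FPKM. Tuba3a (16.6 against 27.8 FPKM, adjusted p = 0.109) and Mael (3.38 against 5.93 FPKM, adjusted p = 0.184) did not pass. Zscan4, Xlr, Rhox2, Magea and Tuba3 genes belong to families of near-identical copies, so reads shared between copies leave the value of each single member uncertain here and in every comparison that follows.

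Other genes with large decreases in H3.1K9M were Zfp951, from 3.67 ± 0.0516 to 0.801 ± 0.162 FPKM, Arl14epl, from 9.84 ± 0.956 to 3.92 ± 0.658, and the kinase gene Wnk3, from 4.86 ± 0.471 to 1.95 ± 0.244. Fkbp6, which acts in meiosis, fell 2.63-fold. Of 6 tested genes on chromosome Y 2 fell. The ubiquitin-activating enzyme gene Uba1y, outside the Y-linked list, fell from 7.76 ± 0.468 to 2.54 ± 0.231 FPKM (limma adjusted p = 0.00292). Of 5 genes in that list, Zfy1 fell, from 1.26 ± 0.108 to 0.225 ± 0.0689 FPKM, and adjusted over the list alone 4 fell, with a median of −0.40 (camera adjusted p = 5.33e-06; adjusted p = 0.139 with an estimated correlation). Ddx3y (5.72 against 8.47 FPKM), Eif2s3y (18.6 against 24.5 FPKM) and Kdm5d (0.437 against 0.761 FPKM) had adjusted p values of 0.107, 0.28 and 0.354. The nucleotide-hydrolysing ectoenzyme gene Enpp3 rose from 5.09 ± 0.608 to 9.97 ± 1.31 FPKM, and Creld1 from 11.4 ± 0.892 to 16.8 ± 0.309.

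Of 26 pluripotency genes 1 fell in H3.1K9M, and adjusted over the list alone 6 fell, with a median of −0.18 (camera adjusted p = 6.94e-05; adjusted p = 0.432 with an estimated correlation). Tbx3, a T-box factor of naive stem cells, fell from 23.5 ± 3.97 to 11.4 ± 2.49 FPKM, while Fbxo15 (48.3 against 87.0 FPKM, adjusted p = 0.0536), Zfp42 (287 against 404 FPKM, adjusted p = 0.209) and Rex2 (5.32 against 9.83 FPKM, adjusted p = 0.214) did not pass. No member of 22 immediate early genes passed over all genes, and adjusted over the list alone 6 rose, with a median of 0.44 (adjusted p = 1.37e-09; adjusted p = 0.105 with an estimated correlation). Junb (54.3 against 38.1 FPKM), Cyr61 (63.5 against 37.4), Dusp6 (27.9 against 18.1) and Fos (59.9 against 41.7) had adjusted p values between 0.203 and 0.276. Of 30 fibroblast feeder markers none passed, also adjusted over the list alone, at a median of 0.74 (adjusted p = 9.86e-11; adjusted p = 0.491 with an estimated correlation). Their mean log2 level was 5.06 and 4.23 in the H3.1K9M libraries and 3.67 and 4.34 in the H3.1WT libraries, and Postn (6.41 ± 2.86 against 2.54 ± 0.964 FPKM), Col6a2 (7.98 against 4.34) and Ctgf (103 against 58.8) did not pass. With the feeder marker mean as a covariate, chosen after seeing the data, the pluripotency list had an adjusted p of 0.0543 and the feeder list one of 0.916. The covariate is built from the feeder list's own genes, so the value for that list tells nothing.

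None of 24 mismatch repair genes passed in H3.1K9M, also adjusted over the list alone. Their median log2 fold change was −0.11 (camera adjusted p = 0.0122; adjusted p = 0.596 with an estimated correlation). The adjusted p was 0.0577 without H3.1WT replicate 2 and 0.758 with the feeder marker covariate, and it was 0.912 without H3.1K9M replicate 1, where the direction turned. Pold4 (11.6 against 8.29 FPKM), Rfc4 (45.6 against 56.3), Rfc2 (51.6 against 60.5) and Lig1 (70.7 against 84.0) had adjusted p values of 0.234 to 0.469. The shift was not particular to mismatch repair. None of 26 homologous recombination genes passed, at a median of −0.125 (camera adjusted p = 0.00961; adjusted p = 0.586 with an estimated correlation). Base and nucleotide excision repair genes each had a median of −0.08 (camera adjusted p = 0.173 and 0.16). None of 22 writers, readers and erasers of H3K9 methylation passed, also adjusted over the list alone, at a median of −0.02 (camera adjusted p = 0.515), which became 0.036 without H3.1K9M replicate 2. Among them were the methyltransferase genes Ehmt2 (56.0 against 47.3 FPKM), Setdb1 (20 against 22.9) and Setdb2 (3.68 against 4.38), and Atf7ip (18.8 against 22.0), with adjusted p values of 0.327 to 0.471.

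By limma's test with Benjamini-Hochberg adjustment, 41 of 13109 genes changed between H3.1K9M and H3.1WT, 3 upward and 38 downward, and 1465 had an unadjusted p under 0.05. The count was 2 without H3.1WT replicate 1, 4 without H3.1WT replicate 2, 20 without H3.1K9M replicate 1 and 695 without H3.1K9M replicate 2. Of 18 called genes named for this comparison, 1, 2, 6 and 18 still passed in the same order.

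H3.1K36M was compared with H3.1WT to ask which transcripts differed when methylation of H3K36, a mark of transcribed gene bodies, was targeted. Among the genes that rose were 11 of 19 X-linked Rhox, Xlr and Mage genes and 4 of 26 pluripotency genes. Among those that fell were 7 of 16 primitive streak, 6 of 16 trophectoderm and 5 of 11 primed genes, and none of these lists passed with an estimated correlation. Xlr3c (chromosome X, 73254540 to 73265390) rose from 1.73 ± 0.532 to 23.5 ± 0.375 FPKM (SD, n = 2), a log2 fold change of 3.18 (limma adjusted p = 2.24e-05). Krt8 (chromosome 15, 101996698 to 102004482), a keratin of simple epithelia, fell from 55.7 ± 1.94 to 5.42 ± 0.0993 FPKM (adjusted p = 1.18e-05), and its partner Krt18 from 38.8 ± 0.62 to 5.78 ± 0.0249. Otx2, a homeobox factor of the primed state, fell from 16.4 ± 0.12 to 1.82 ± 0.208 FPKM (adjusted p = 4.69e-05). Nanog, a core pluripotency factor, rose from 192 ± 10.7 to 376 ± 3.39 FPKM (adjusted p = 0.0129).

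Of 19 X-linked Rhox, Xlr and Mage genes, 11 rose in H3.1K36M, and adjusted over the list alone 15 rose. None fell, and the median log2 fold change was 0.93 (camera adjusted p = 2.57e-17; adjusted p = 0.0524 with an estimated correlation). Xlr5b rose from 0.773 ± 0.253 to 9.05 ± 0.0756 FPKM, Xlr5a from 1.11 ± 0.288 to 8.27 ± 0.466 and Magea5 from 0.159 ± 0.0231 to 2.35 ± 0.405. Xlr5c and Rhox2a, which are not in that list, rose from 0.452 ± 0.00889 to 6.96 ± 1.71 and from 0.63 ± 0.413 to 10.95 ± 0.384. On chromosome X as a whole 49 of 444 tested genes rose and 10 fell, with a median of 0.0961. In the 2-cell-like list 4 of 17 rose, and adjusted over the list alone 8 rose, with a median of 0.44 (adjusted p = 4.76e-05; adjusted p = 0.477 with an estimated correlation). Zscan4a rose from 3.16 ± 0.799 to 9 ± 1.35 FPKM and Tmem92 from 2.74 ± 0.696 to 7.99 ± 0.867, while Pramel7 rose from 0.404 to 2.2 FPKM and Pramel6 from 0.22 to 1.66. None of these 4 genes still passed with the feeder marker covariate, or with a pseudocount of 0.1. Germline genes silenced by promoter DNA methylation were divided: 7 of 26 rose and none fell over all genes, 8 rose and 4 fell adjusted over the list alone, and the median was 0.07 (adjusted p = 0.443). The oocyte gene Nlrp4c, outside these lists, rose from 1.18 ± 0.028 to 5.61 ± 0.0876 FPKM.

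Naive and general pluripotency genes had a median of 0.22 in H3.1K36M, with 4 of 26 risen and none fallen (camera adjusted p = 0.00619; adjusted p = 0.533 with an estimated correlation). Adjusted over the list alone, 9 rose and 1 fell. Besides Nanog, Tfcp2l1 rose from 17.7 ± 1.23 to 33.8 ± 0.8 FPKM, Fgf4 from 29.8 ± 0.277 to 47.7 ± 1.14 and the germ cell and naive factor Prdm14 from 4.79 ± 1.15 to 8.43 ± 0.125. Fgf4 no longer passed with quantile normalization. Prdm14 no longer passed with quantile or median-of-ratios scaling, a pseudocount of 0.1 or the feeder marker covariate. Of 11 genes of primed or formative pluripotency 5 fell, also adjusted over the list alone, with a median of −0.16 and a mean of −0.66 (adjusted p = 2.73e-05; adjusted p = 0.0524 with an estimated correlation). Lef1, a Wnt pathway transcription factor, fell from 11.4 ± 0.988 to 1.79 ± 0.0324 FPKM, Grhl2 from 4.14 ± 0.49 to 1.65 ± 0.0954 and the kinase gene Pim2 from 30.2 ± 4.64 to 14.8 ± 0.248. Among 16 primitive streak and mesoderm genes 7 fell, and adjusted over the list alone 7 fell and 1 rose, with a median of −0.24 (adjusted p = 3.72e-06; adjusted p = 0.193 with an estimated correlation). T, the brachyury gene, fell from 9.37 ± 2.74 to 0.812 ± 0.239 FPKM (limma adjusted p = 0.00113), Mixl1 from 3.60 ± 0.714 to 0.772 ± 0.213, Hand1 from 4.29 ± 0.499 to 1.07 ± 0.0965 and Evx1 from 1.21 ± 0.27 to 0.0779 ± 0.0122. The control H3.1WT itself stood above the control shNC in the primed and primitive streak lists, with medians of 0.35 and 0.29, and Lef1 was at 5.58 FPKM in shNC.

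In the trophectoderm and placenta list 6 of 16 genes fell and 1 rose in H3.1K36M, and adjusted over the list alone 9 fell and 3 rose, with a median of −0.53 (camera adjusted p = 3.91e-05; adjusted p = 0.193 with an estimated correlation). Cdx2, a trophectoderm transcription factor, fell from 3.45 ± 0.917 to 0.184 ± 0.0636 FPKM beside Krt8, Krt18 and Hand1. In the control shNC Cdx2 stood at 0.155 FPKM and Krt8 at 13.5 FPKM, lower than in H3.1WT. Of 26 genes of the ATF4 and unfolded protein response 4 fell, and adjusted over the list alone 7 fell and 2 rose, with a median of −0.21 (adjusted p = 0.000494; adjusted p = 0.351 with an estimated correlation). Atf3 fell from 14.3 ± 3.19 to 4.85 ± 0.258 FPKM, Stc2 from 23.9 ± 2.3 to 12.2 ± 0.385, Atf4 from 81.8 ± 0.601 to 57.4 ± 0.599 and Pck2 from 10.7 ± 0.465 to 6.83 ± 0.556. Further genes with large decreases were the interferon-inducible guanylate-binding genes Gbp2, from 7.30 ± 1.58 to 1.20 ± 0.121 FPKM, and Gbp1, from 4.19 ± 1.23 to 0.398 ± 0.0621. Cyp26a1, which degrades retinoic acid, fell from 4.27 ± 0.865 to 0.739 ± 0.081 FPKM and Vrtn from 4.13 ± 0.386 to 0.738 ± 0.00725.

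Primitive and visceral endoderm genes had a median of 0.32 in H3.1K36M, with 4 of 21 risen and 1 fallen, and 9 and 1 adjusted over the list alone (camera adjusted p = 0.00813; adjusted p = 0.302 with an estimated correlation). With the feeder marker covariate this list had an adjusted p of 0.0839. The laminin gene Lama1 rose from 9.73 ± 0.485 to 23.0 ± 0.14 FPKM, Cited1 from 3.72 ± 0.159 to 8.11 ± 0.0653 and Amn from 2.62 ± 0.457 to 5.33 ± 0.285, whereas the endoderm factor Gata4 fell from 1.54 ± 0.0434 to 0.748 ± 0.0711. Of 30 fibroblast feeder markers 3 rose, and adjusted over the list alone 4 rose, with a median of 0.71 (adjusted p = 3.72e-06; adjusted p = 0.631 with an estimated correlation). With the covariate, built from these same genes, their direction turned (adjusted p = 0.489). Their mean log2 level was 4.73 and 4.72 in the H3.1K36M libraries against 3.67 and 4.34 in H3.1WT. Postn rose from 2.54 ± 0.964 to 10.5 ± 0.331 FPKM, Col3a1 from 7.08 ± 4 to 22.5 ± 0.00304 and Col6a2 from 4.34 ± 0.935 to 8.67 ± 0.131, and Thy1 (22.4 against 16.9 FPKM) had an adjusted p of 0.0631. The secreted protease gene Htra1 rose from 9.18 ± 1.79 to 31.3 ± 1.41 FPKM and Fabp7, a fatty acid binding protein gene, from 0.80 ± 0.455 to 6.15 ± 0.493.

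None of 25 writers, readers and erasers of H3K36 methylation passed in H3.1K36M, also adjusted over the list alone, at a median of −0.003 (camera adjusted p = 0.576). Setd2, the main H3K36 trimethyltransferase gene, stood at 18.6 ± 0.389 FPKM against 16.7 ± 0.284 (limma adjusted p = 0.294), Kdm4b at 11.5 against 15.7, Phf1 at 4.8 against 3.74 and Phf19 at 2.56 against 3.11 (adjusted p of 0.155 to 0.4). None of 24 mismatch repair genes passed either, also adjusted over the list alone, at a median of −0.06 (camera adjusted p = 0.136). Ssbp1 (35.5 against 41.1 FPKM), Pold4 (6.80 against 8.29) and Pold3 (17.9 against 20.8) had adjusted p values of 0.258, 0.259 and 0.402.

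In all, 634 genes changed between H3.1K36M and H3.1WT, 406 upward and 228 downward, 109 of them by at least 1 on the log2 scale. Quantile normalization gave 317 upward and 273 downward, and median-of-ratios scaling 320 and 257, so the share that rose was 64% as deposited, 53.7% and 55.5%. The count was 131 and 200 without H3.1WT replicates 1 and 2, 108 and 107 without H3.1K36M replicates 1 and 2, and 1185 without H3.1K9M replicate 1, which enters only the estimate of spread. Of 44 called genes named for this comparison, 25, 29, 23, 22 and 44 still passed in the same order.

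The direct comparison of H3.1K36M with H3.1K9M, which uses no control library, asks how the effects of the mutants differed. Xlr3c stood at 23.5 ± 0.375 FPKM (SD, n = 2) in H3.1K36M and 0.639 ± 0.176 in H3.1K9M, a log2 fold change of 3.91 (limma adjusted p = 3.62e-06). Fkbp6 was 8.09-fold higher, at 11.2 ± 0.172 against 1.38 ± 0.118 FPKM, and Dazl 6.26-fold higher. Krt8 was 8.64-fold lower, at 5.42 ± 0.0993 against 46.8 ± 11.3 FPKM, and T 11.7-fold lower.

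Among 19 X-linked Rhox, Xlr and Mage genes 16 were higher in H3.1K36M, and adjusted over the list alone 18, with a median of 1.54 (camera adjusted p = 5.06e-24). This call held with an estimated correlation (adjusted p = 0.0251), and it was the only list call in any of the comparisons that did. Xlr5b and Xlr5a stood at 0.31 and 0.393 FPKM in H3.1K9M, and Magea5 was listed at 0 in both H3.1K9M libraries. Xlr5c and Rhox2a, outside the list, stood at 0.0505 and 0.463 FPKM there. In the 2-cell-like list 15 of 17 were higher, and adjusted over the list alone 16, with a median of 1.40 (adjusted p = 1.33e-16; adjusted p = 0.0886 with an estimated correlation). Zscan4d was at 7.80 ± 0.0361 against 1.05 ± 0.302 FPKM, Zscan4c at 8.60 ± 0.78 against 1.92 ± 0.217, Zscan4f at 17.3 ± 1.51 against 3.73 ± 0.88, Zscan4e at 3.76 against 0.702, and Tmem92 at 7.99 ± 0.867 against 0.874 ± 0.662. Of 26 germline genes silenced by promoter DNA methylation 9 were higher and 1 lower, and adjusted over the list alone 16 and 2, with a median of 0.57 (adjusted p = 4.17e-06; adjusted p = 0.206 with an estimated correlation). Tuba3a was at 65.0 ± 1.03 against 16.6 ± 4.11 FPKM, the piRNA pathway gene Asz1 at 2.52 against 0.186 and the ribosomal protein retrogene Rpl10l at 96.9 ± 5.82 against 37.5 ± 1.66. Outside these lists, Arl14epl was at 22.1 ± 0.439 against 3.92 ± 0.658 FPKM and Nlrp4c at 5.61 ± 0.0876 against 0.318 ± 0.00466.

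Pluripotency genes were higher in H3.1K36M than in H3.1K9M for 12 of 26 members, and for 14 adjusted over the list alone, with a median of 0.50 (camera adjusted p = 1.61e-06; adjusted p = 0.206 with an estimated correlation). Nanog stood at 376 ± 3.39 against 123 ± 18.5 FPKM, Tfcp2l1 at 33.8 ± 0.8 against 16.1 ± 3.36, Fbxo15 at 104 ± 2.83 against 48.3 ± 6.51 and Prdm14 at 8.43 ± 0.125 against 3.03 ± 0.369. Of 16 primitive streak and mesoderm genes 8 were lower, and adjusted over the list alone 11, with a median of −0.54 (adjusted p = 7.75e-08; adjusted p = 0.0886 with an estimated correlation). Fgf8 was at 0.882 ± 0.108 against 3.91 ± 1.08 FPKM, Hand1 at 1.07 against 3.14 and Nkx2-5 at 0.212 against 0.765. Also lower were Krt18 (5.83-fold), Lef1 (5.96-fold), Gbp2 (6.34-fold), Gbp1 (9.6-fold), Otx2 (4.37-fold), Enpp3 (4.2-fold), Mef2b (4.33-fold) and the carbonic anhydrase gene Car2, at 7.01 ± 0.193 against 22.2 ± 1.19 FPKM. Imprinted genes went both ways, 2 of 30 higher and 6 lower, or 3 and 11 adjusted over the list alone, with a median of −0.13 (adjusted p = 0.00522; adjusted p = 0.0886 with an estimated correlation; adjusted p = 0.0777 without H3.1K9M replicate 1). Rian, Peg10 and Peg3 were 1.64-fold, 2.33-fold and 2.33-fold lower, and Plagl1 1.82-fold higher. Suv39h1 was 1.53-fold lower (adjusted p = 0.0127). Feeder markers stood alike in the mutants, with none of 30 called and a median of 0.02 (adjusted p = 0.911).

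Of 24 mismatch repair genes only Pold4, a subunit gene of DNA polymerase delta, differed between the mutants, at 6.80 ± 0.299 FPKM in H3.1K36M against 11.6 ± 0.316 in H3.1K9M (limma adjusted p = 0.00761), also adjusted over the list alone. The list's median was 0.09 (camera adjusted p = 0.718), and its adjusted p was 0.00938 without H3.1K9M replicate 2. Msh6 (128 against 111 FPKM), Lig1 (85.4 against 70.7) and Rfc4 (53.7 against 45.6) had adjusted p values of 0.195 to 0.279. The comparison called 1080 genes, 730 higher and 350 lower in H3.1K36M, 183 of them by at least 1 on the log2 scale. On chromosome 16, whose 372 tested genes had a median of 0.192, 64 were higher and 3 lower, and on chromosome X 70 and 15. Leaving out chromosomes 11, 16, 19 and Y, chosen after seeing the data, gave 864 called genes. Quantile normalization gave 566 and 390 and median-of-ratios scaling 542 and 453, which put the higher share at 67.6% as deposited, 59.2% and 54.5%. Without H3.1K36M replicate 1 or 2 the count was 267 or 273, and 34 of 41 called genes named here still passed in either case.

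shSuv39h1 was compared with shNC to ask what a lower level of Suv39h1 changed, with the knockdown itself short of the threshold as given above. Few genes passed. Atf4, the transcription factor of the amino acid and stress response, rose from 51.9 ± 4.63 to 95.6 ± 0.652 FPKM (SD, n = 2; limma adjusted p = 0.0224). Fkbp6 (chromosome 5, 135291704 to 135350044) fell from 9.09 ± 0.555 to 2.59 ± 0.29 FPKM (adjusted p = 0.00247), and the Y-linked Uba1y from 7.04 ± 0.782 to 2.08 ± 0.0591 (adjusted p = 0.00175). Interferon response genes lay lower as a list by camera, with no single member past the test and no call with an estimated correlation.

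Among 27 interferon response genes all were lower in shSuv39h1, none passed over all genes, and adjusted over the list alone 12 fell. The median was −0.55 (camera adjusted p = 1.7e-18; adjusted p = 0.22 with an estimated correlation). The list was also lower in the other control line than in shNC, with a median of −0.38 and 21 of 27 genes lower in H3.1WT (adjusted p = 1.24e-05; adjusted p = 0.642 with an estimated correlation). Ifi35 (9.75 against 14.1 FPKM), Ifitm3 (99.7 against 197), Oas1a (4.86 against 8.73) and Oasl2 (0.549 against 2.06) had adjusted p values of 0.129 to 0.185. Feeder markers lay lower as well. None of 30 passed, also adjusted over the list alone, at a median of −0.43 (camera adjusted p = 4.33e-10; adjusted p = 0.569 with an estimated correlation; 0.402 with the feeder covariate, which is built from these same genes). Their mean log2 level was 3.94 and 3.49 in shSuv39h1 and 3.91 and 4.35 in shNC, and Mmp2 (13.6 against 19 FPKM), Pdgfrb (4.57 against 5.91), Ctgf (46.6 against 71.0) and Cyr61 (27.8 against 40.5) had adjusted p values of 0.3 to 0.442. Of 17 genes of the 2-cell-like list none passed, and adjusted over the list alone 3 fell, with a median of −0.40 (adjusted p = 1.27e-10; adjusted p = 0.22 with an estimated correlation). Zscan4c (3.21 against 6.32 FPKM), Zscan4e (1.46 against 2.59), Tmem92 (1.59 against 3.82) and Zfp809 (9.62 against 12.6) had adjusted p values of 0.133 to 0.361.

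Of 19 X-linked Rhox, Xlr and Mage genes 2 fell in shSuv39h1, and adjusted over the list alone 6 fell and 1 rose, with a median of −0.28 (camera adjusted p = 2.34e-06; adjusted p = 0.22 with an estimated correlation). Rhox9 fell from 11 ± 0.135 to 4.87 ± 0.229 FPKM and Rhox5 from 83.3 ± 1.06 to 47.7 ± 4.19, and Xlr5a (0.52 against 1.42 FPKM) and Rhox1 (2.63 against 5.37) each had an adjusted p of 0.0885. In the Y-linked list, without Uba1y, 2 of 5 fell, and adjusted over the list alone 4 fell, with a median of −0.73 (adjusted p = 5.71e-11; adjusted p = 0.0792 with an estimated correlation). Ddx3y, an RNA helicase gene, fell from 8.84 ± 1.19 to 3.67 ± 0.00472 FPKM and the demethylase homologue Uty from 2.57 ± 0.0149 to 1.16 ± 0.187. Eif2s3y (13.8 against 23.8 FPKM, adjusted p = 0.0608) and Zfy1 (0.293 against 0.758 FPKM, adjusted p = 0.19) did not pass. The elongin B gene Tceb2 fell from 457 ± 23.3 to 313 ± 1.48 FPKM.

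Of 26 genes of the ATF4 and unfolded protein response Atf4 alone passed in shSuv39h1, and adjusted over the list alone 7 rose, with a median of 0.22 (camera adjusted p = 9.32e-05; adjusted p = 0.22 with an estimated correlation). The list was also higher in H3.1WT than in shNC, with a median of 0.16 and 20 of 26 genes higher (adjusted p = 0.00277; adjusted p = 0.426 with an estimated correlation), and Atf4 stood at 81.8 FPKM in H3.1WT. Herpud1 (16.8 against 9.57 FPKM), Chac1 (12.5 ± 1.8 against 4.62 ± 2.95) and Pck2 (11.5 against 7.79) had adjusted p values of 0.145 to 0.211. Tmem141 rose from 4.50 ± 0.503 to 10.5 ± 0.905 FPKM, Lama1 from 9.21 ± 0.426 to 18.4 ± 0.0117 and the axon guidance gene Ntn1 from 5.44 ± 0.345 to 10.8 ± 0.235. Smaller rises were those of Nagk (1.66-fold), the imprinted transcript Rian (1.55-fold), Gfod2 (1.53-fold), Cltb (1.4-fold), Etv4 (1.4-fold) and Itpk1 (1.38-fold). These calls depended on the scaling. None of these genes passed with median-of-ratios scaling, and of them Nagk alone passed with quantile normalization. None of 24 mismatch repair genes passed, also adjusted over the list alone, at a median of 0.12 (adjusted p = 0.0792; 0.02 without shNC replicate 2 and 0.0452 without shSuv39h1 replicate 1). Rpa3 (51.5 against 42.9 FPKM), Pms2 (9.03 against 7.45), Mlh3 (6.95 against 5.60) and Ssbp1 (42.6 against 37.0) had adjusted p values of 0.311 to 0.509.

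limma called 19 genes between shSuv39h1 and shNC, 11 upward and 8 downward, with 1384 at an unadjusted p under 0.05. Quantile normalization gave 8 and 11 and median-of-ratios scaling 5 and 9, so the share that rose was 57.9% as deposited, 42.1% and 35.7%. The count was 3 without shNC replicate 1, 2 without shSuv39h1 replicate 2 and 58 without H3.1K9M replicate 1. Without shSuv39h1 replicate 1 limma called 0, with 905 genes at an unadjusted p under 0.05, and of 17 called genes named here 3, 5, 0 and 2 still passed without shNC replicates 1 and 2 and shSuv39h1 replicates 1 and 2.

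shSuv39h2 was compared with shNC to ask what a lower level of Suv39h2 changed. Among the genes that fell were 14 of 17 in the 2-cell-like list, 13 of 19 X-linked Rhox, Xlr and Mage genes, 11 of 26 germline genes and 5 of 6 genes on chromosome Y, and among those that rose were 10 of 26 in the ATF4 list. None of these lists, nor the Y-linked list, passed with an estimated correlation. Fkbp6 fell from 9.09 ± 0.555 to 1.22 ± 0.219 FPKM (SD, n = 2), a log2 fold change of −2.19 (limma adjusted p = 2.88e-05). Zscan4c fell from 6.32 ± 1.93 to 0.484 ± 0.0966 FPKM (adjusted p = 0.000161), and Uba1y from 7.04 ± 0.782 to 0.867 ± 0.000282 (adjusted p = 1.39e-05). Atf4 (chromosome 15, 80255184 to 80257541) rose from 51.9 ± 4.63 to 118 ± 12.9 FPKM (adjusted p = 0.00034).

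In the 2-cell-like list 14 of 17 genes fell in shSuv39h2, and adjusted over the list alone all 17, with a median of −1.02 (camera adjusted p = 3.74e-17; adjusted p = 0.189 with an estimated correlation). Zscan4f fell 8.21-fold, Zscan4d 8.2-fold and Zscan4e 15.3-fold. Of 19 X-linked Rhox, Xlr and Mage genes 13 fell, and adjusted over the list alone 16, with a median of −0.85 (adjusted p = 3.74e-17; adjusted p = 0.0635 with an estimated correlation). Xlr3b fell from 7.69 ± 0.67 to 0.781 ± 0.103 FPKM, Xlr3a from 10.0 ± 0.488 to 2.27 ± 0.203, Rhox5 from 83.3 ± 1.06 to 32.1 ± 4.59 and Rhox1 from 5.37 ± 0.506 to 0.726 ± 0.218. Other X-linked genes with large decreases were Pnma5, from 16.8 ± 0.538 to 3.07 ± 0.321 FPKM, and Fmr1nb, from 59.0 ± 2.97 to 12.9 ± 1.54. Among 26 germline genes silenced by promoter DNA methylation 11 fell, and adjusted over the list alone 15 fell and 1 rose, with a median of −0.46 (adjusted p = 6.35e-10; adjusted p = 0.2 with an estimated correlation). Tuba3a fell from 39.2 ± 1.82 to 16.1 ± 1.62 FPKM, the testis cytochrome c gene Cyct from 17.5 ± 2.88 to 5.60 ± 0.881, Dazl from 5.05 ± 1.16 to 1.76 ± 0.0817 and Tex101 from 4.21 ± 0.541 to 1.18 ± 0.338. Arl14epl, outside these lists, fell 4.25-fold.

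**Figure D2:**
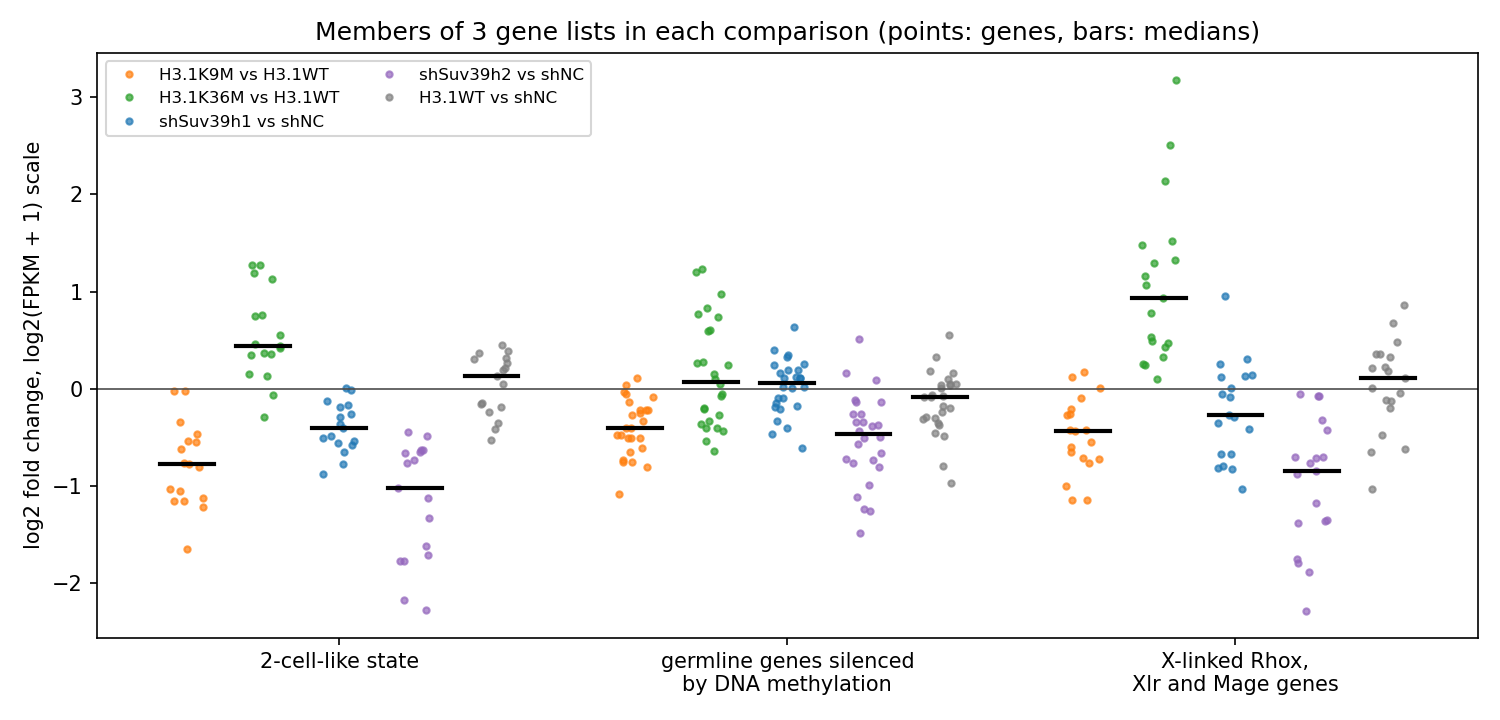
Log2 fold change, on the log2(FPKM + 1) scale, of the tested members of 3 gene lists (horizontal axis) in 5 comparisons (colours), with a point per gene and a bar at each median. The medians of the X-linked list are 0.93 in H3.1K36M, −0.43 in H3.1K9M, −0.28 in shSuv39h1 and −0.85 in shSuv39h2, each against its own control.

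In the Y-linked list, which does not include Uba1y, 4 of 5 genes fell in shSuv39h2, also adjusted over the list alone, with a median of −1.13 (camera adjusted p = 2.31e-08; adjusted p = 0.0854 with an estimated correlation). Ddx3y fell from 8.84 ± 1.19 to 1.51 ± 0.0755 FPKM, Eif2s3y from 23.8 ± 1.32 to 6.45 ± 0.00857, Uty from 2.57 ± 0.0149 to 0.634 ± 0.117 and Zfy1 from 0.758 ± 0.0384 to 0.047 ± 0.00739. In the interferon response list 6 of 27 fell, and adjusted over the list alone 10, with a median of −0.45 (adjusted p = 2.51e-07; adjusted p = 0.41 with an estimated correlation). As in shSuv39h1, this list stood lower in the control line H3.1WT than in shNC (median −0.38). Oas1a, an RNA sensor gene, fell from 8.73 ± 1.27 to 3.03 ± 0.955 FPKM. Xaf1 fell 2.85-fold, Ifi35 1.71-fold and the transcription factor gene Irf1 1.74-fold, and these last 3 lie on chromosome 11, whose genes had a median log2 fold change of −0.22. Ifi27l1, outside this list, fell from 46.1 ± 23.4 to 10.9 ± 1.22 FPKM. Feeder markers did not move as a list: 2 of 30 fell, also adjusted over the list alone, with a median of 0.06, a mean of 0.004 and a test direction downward (adjusted p = 0.335). Their mean log2 level was 4.24 and 4.03 in shSuv39h2 against 3.91 and 4.35 in shNC. Thy1 fell from 21 ± 0.0899 to 14.3 ± 0.179 FPKM and Mmp2 from 19 ± 2.92 to 11.8 ± 2.23, and Pdgfrb (4.54 against 5.91 FPKM, adjusted p = 0.144) and Fbln1 (14.1 against 17.7 FPKM, adjusted p = 0.275) did not pass.

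Of 26 genes of the ATF4 and unfolded protein response 10 rose in shSuv39h2, and adjusted over the list alone 12, with a median of 0.33 (camera adjusted p = 0.000365; adjusted p = 0.261 with an estimated correlation). Between the control lines the list stood 0.16 higher at the median in H3.1WT than in shNC, with Atf4 at 81.8 against 51.9 FPKM. Chac1, a glutathione-degrading enzyme gene, rose from 4.62 ± 2.95 to 17.5 ± 0.553 FPKM, the mitochondrial carboxykinase gene Pck2 from 7.79 ± 0.32 to 15.2 ± 1.29 and the amino acid transporter gene Slc3a2 from 109 ± 2.84 to 158 ± 9.03. The transcription factor gene Pou4f2 rose from 1.00 ± 0.0846 to 5.26 ± 1.43 FPKM, Gbx2 from 7.29 ± 3.79 to 22.4 ± 7.19 and Dmrt1, a gonadal factor, from 7.90 ± 0.991 to 19.2 ± 0.255. Ntn1 rose 2.49-fold, Stmn3 3.28-fold, Mia 3.07-fold, the RNA polymerase III subunit gene Polr3gl 2.64-fold, Sssca1 2.29-fold and Enpp3 2.39-fold. Slc3a2, Dmrt1 and Sssca1 lie on chromosome 19, whose genes had a median of 0.34. Of 296 zinc finger genes 18 rose and 4 fell, or 13 and 3 adjusted over the list alone, with a median of 0.13 (adjusted p = 0.0303; adjusted p = 0.346 with an estimated correlation; 0.0963 without shNC replicate 1 and 0.0689 without shSuv39h2 replicate 2). These genes had a median of 0.09 in H3.1WT against shNC (adjusted p = 0.00733; adjusted p = 0.374 with an estimated correlation). Zfp951 fell from 4.07 ± 0.839 to 0.355 ± 0.257 FPKM and Zfp600 from 9.26 ± 1.96 to 3.88 ± 1.01, while Zfp553 rose 1.75-fold and Zfp691 1.77-fold.

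Among 23 base excision repair genes 6 rose in shSuv39h2, also adjusted over the list alone, with a median of 0.15 (camera adjusted p = 0.04; adjusted p = 0.616 with an estimated correlation). The camera adjusted p was 0.093 at a minimum of 5 FPKM and 0.0771 with quantile normalization. It was 0.0712 in the fit over the arm and 0.0539 in that over the compared pair, and fry gave an adjusted p of 0.0773. The adjusted p was 0.0621 without shNC replicate 1, 0.0757 without shSuv39h2 replicate 2, 0.0569 without H3.1K9M replicate 1 and 0.0538 with the feeder covariate. The glycosylase gene Neil1 rose from 3.85 ± 0.0944 to 5.74 ± 0.476 FPKM, the scaffold gene Xrcc1 from 36 ± 4.91 to 48.3 ± 3.7 and Parp2 from 24.5 ± 1.38 to 32.2 ± 1.35. Of 24 mismatch repair genes Pold4, on chromosome 19, rose from 7.79 ± 0.143 to 13.4 ± 2.4 FPKM (limma adjusted p = 0.00713), also adjusted over the list alone. The list's median was 0.13 (camera adjusted p = 0.192; 0.0292 without shSuv39h2 replicate 1). Pcna (257 against 209 FPKM) and Rpa2 (57.0 against 47.6) had adjusted p values of 0.14 and 0.16.

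limma called 1316 genes between shSuv39h2 and shNC, 701 upward and 615 downward, 127 of them by at least 1 on the log2 scale. Quantile normalization gave 554 and 653 and median-of-ratios scaling 547 and 722, and the share that rose was 53.3% as deposited, 45.9% and 43.1%. The count was 592 without shNC replicate 1, 360 and 402 without shSuv39h2 replicates 1 and 2 and 1998 without H3.1K9M replicate 1. Of 51 called genes chosen by the naming rule 43, 39, 40 and 51 still passed in the same order.

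Whole chromosomes stood apart in these comparisons. In shSuv39h2 the 1083 tested genes of chromosome 11 had a median log2 fold change of −0.22 and the 424 genes of chromosome 19 one of 0.34, against shNC. Chromosome 11 held 174 of the 615 genes that fell, and chromosome 19 held 147 of the 701 that rose. In H3.1K36M the 372 genes of chromosome 16 had a median of 0.20 against H3.1WT, with 39 risen and 1 fallen. Chromosome X stood higher there too, though by less, with a median of 0.0961 over 444 genes. On it 49 genes rose and 10 fell. Leaving out chromosomes 11, 16, 19 and Y, an alternative chosen after seeing the data, gave 814 called genes in shSuv39h2 and 367 between the knockdowns. The pattern was seen in each library. As deviations from the gene means over all libraries, chromosome 11 stood at −0.225 and −0.199 in the shSuv39h2 libraries, chromosome 19 at 0.228 and 0.243, and chromosome 16 at 0.152 and 0.15 in the H3.1K36M libraries.

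**Figure D3:**
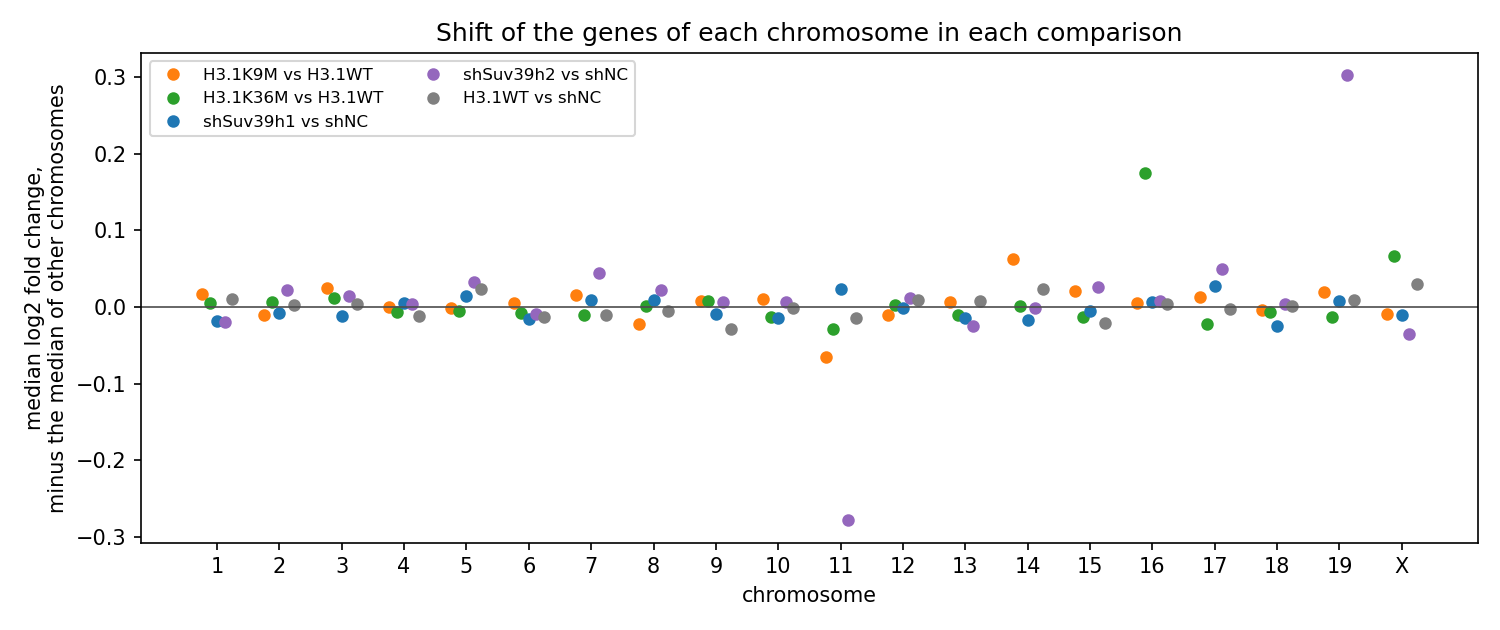
Median log2 fold change of the tested genes of each autosome and chromosome X, minus the median of genes on all other chromosomes (vertical axis, log2(FPKM + 1) scale), in 5 comparisons (colours). Chromosomes 11 and 19 in shSuv39h2 stand at −0.278 and 0.302, and chromosome 16 in H3.1K36M stands at 0.175.

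shSuv39h1 was also compared directly with shSuv39h2, without control libraries, to ask how the knockdowns differed. Suv39h1 was 2.02-fold lower in shSuv39h1, at 5.01 ± 0.136 against 10.1 ± 0.544 FPKM (SD, n = 2; limma adjusted p = 0.00296), and Suv39h2 2.98-fold higher, at 5.02 ± 0.229 against 1.68 ± 0.104 (adjusted p = 0.000514). Higher in shSuv39h1 were 11 of 26 germline genes and 11 of 19 X-linked Rhox, Xlr and Mage genes, and neither list passed with an estimated correlation. On chromosome X as a whole 40 of 444 genes were higher and 4 lower, with a median of 0.03. Chromosome 11 held 219 of the 598 genes higher in shSuv39h1 (median 0.28 over its 1083 tested genes), and chromosome 19 held 104 of the 262 lower ones (median −0.30 over 424). Pnma5 stood at 18.9 ± 2.06 against 3.07 ± 0.321 FPKM (adjusted p = 9.76e-06) and Fmr1nb at 56 ± 0.192 against 12.9 ± 1.54 (adjusted p = 3.33e-05). The calcium-binding protein gene Calb2 was at 13.8 ± 1 against 2.45 ± 0.348 FPKM.

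Of 19 X-linked Rhox, Xlr and Mage genes 11 were higher in shSuv39h1 than in shSuv39h2, also adjusted over the list alone, with a median of 0.50 (camera adjusted p = 1.73e-10; adjusted p = 0.202 with an estimated correlation). Xlr3a stood at 12.3 ± 2.44 against 2.27 ± 0.203 FPKM, Rhox10 at 8.07 ± 0.563 against 1.94 ± 0.868, and Xlr3b and Xlr4a were 7.43-fold and 9.98-fold higher. The X-linked Usp26, a testis deubiquitinase gene, was at 11.1 ± 0.1 against 2.11 ± 0.437 FPKM and the mRNA export factor gene Nxf3 at 4.12 ± 0.23 against 0.584 ± 0.0708. In the 2-cell-like list 9 of 17 were higher, and adjusted over the list alone 13, with a median of 0.84 (adjusted p = 4.82e-10; adjusted p = 0.272 with an estimated correlation). Zscan4c, Zscan4f, Zscan4e and Zscan4d were 6.63-fold, 5.39-fold, 8.63-fold and 4.95-fold higher. Of 26 germline genes silenced by promoter DNA methylation 11 were higher, and adjusted over the list alone 16 were higher and 1 lower, with a median of 0.48 (adjusted p = 4.69e-09; adjusted p = 0.21 with an estimated correlation). Cyct stood at 22.4 ± 1.78 against 5.60 ± 0.881 FPKM, Tuba3a at 39.6 ± 1.73 against 16.1 ± 1.62, Tex101 at 3.57 against 1.18 and Syce1 at 22.9 ± 1.08 against 12.2 ± 0.547. Imprinted genes were higher for 5 of 30, also adjusted over the list alone, with a median of 0.20 (adjusted p = 0.036; adjusted p = 0.21 with an estimated correlation; 0.142 without shSuv39h1 replicate 1 and 0.0582 without shSuv39h2 replicate 2). Among them H19 was 1.78-fold, Plagl1 1.8-fold, Phlda2 1.45-fold and Impact 1.4-fold higher. Of 30 feeder markers none passed, also adjusted over the list alone, at a median of −0.50 (adjusted p = 0.0053; adjusted p = 0.85 with an estimated correlation).

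Lower in shSuv39h1 than in shSuv39h2 were Pou4f2, at 1.26 ± 0.244 against 5.26 ± 1.43 FPKM, Stmn3, at 2.28 ± 0.109 against 6.91 ± 0.451, and Sept1, at 25 ± 2.75 against 52.6 ± 3.07. Dmrt1, on chromosome 19, was 2.26-fold lower, Enpp3 2.39-fold, Cdk5r2 2.86-fold, Ildr1 2.29-fold, Fam19a4 2.3-fold and Hsd17b14 1.91-fold. Pold4, also on chromosome 19, was at 9.42 ± 0.964 against 13.4 ± 2.4 FPKM (limma adjusted p = 0.0491), and it did not pass adjusted over the list of 24 mismatch repair genes alone. That list had a median of −0.02 (camera adjusted p = 0.9), and Rpa3 (51.5 against 44.4 FPKM), Rpa1 (125 against 104) and Pold2 (128 against 105) had adjusted p values of 0.17 to 0.348. In all 860 genes differed, 598 higher and 262 lower, 75 of them by at least 1 on the log2 scale. The count was 85 and 76 without shSuv39h1 replicates 1 and 2, 113 and 221 without shSuv39h2 replicates 1 and 2 and 1438 without H3.1K9M replicate 1, and of 33 called genes named here 20, 23, 24, 28 and 33 still passed in that order.

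The mutant and the knockdowns of H3K9 methylation were set side by side because they share a target and use different control libraries. Of 38 genes that fell in H3.1K9M, 32 also fell in shSuv39h2, where independent lists of these sizes would share 1.78. The comparisons come from the same fit and use the same estimate of each gene's spread, so their calls are not fully independent. How far this raises the shared counts was not tested. The shared genes included Zscan4c, Zscan4d, Zscan4e, Xlr3b, Dazl, Fkbp6, Arl14epl, Zfp951 and Uba1y. All 3 genes that rose in H3.1K9M also rose in shSuv39h2, where 0.16 would be shared, and Enpp3 was one of them. Genes that fell in both H3.1K9M and shSuv39h1 were Uba1y and Fkbp6, and none rose in both. Across 13109 genes, which are not independent replicates, the log2 fold changes of H3.1K9M had a Pearson r of 0.302 and a Spearman rho of 0.223 with those of shSuv39h2. With shSuv39h1 they had an r of −0.119 and a rho of −0.209. That r was 0.0873 without H3.1K9M replicate 1, −0.22 without H3.1K9M replicate 2, −0.0416 without shNC replicate 2, −0.19 and −0.00954 without shSuv39h1 replicates 1 and 2.

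Pairs of responses that share a control were compared with 100 simulations of unchanged groups against that control. The simulations gave every group the same spread per gene, averaged over the 6 groups. The real SD of replicate differences was 0.345 in shNC, 0.227 in shSuv39h1 and 0.235 in shSuv39h2. It was 0.26 in H3.1WT, 0.41 in H3.1K9M and 0.223 in H3.1K36M. The simulated values therefore cannot decide whether a pair exceeds what its shared control gives. shSuv39h1 and shSuv39h2 shared 7 genes that rose and 7 that fell, where independent lists would share 0.588 and 0.375, and 1 gene rose in shSuv39h1 and fell in shSuv39h2. Their r was 0.481 against a simulated 0.506, and the covariance 0.0351 against 0.0219. H3.1K9M and H3.1K36M shared 4 genes that fell and none that rose, where 0.661 and 0.0929 would be shared by chance, and 8 genes fell in H3.1K9M and rose in H3.1K36M, where 1.18 would. Their r was 0.345 against a simulated 0.498, with a covariance of 0.0278 against 0.0214. Without H3.1WT replicate 2 that r was 0.559, and without H3.1K9M replicate 1 it was 0.057. The controls could not be split with at least 2 libraries in each part, and how many of the shared calls come from the shared control was not measured.

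The control lines H3.1WT and shNC, which carry neither mutant nor targeting hairpin, differed in 44 genes, 28 higher and 16 lower in H3.1WT. That comparison gives a background for how far separate lines differ, although line and arm differ together and each arm may have been normalized on its own. The count was 14 and 7 without H3.1WT replicates 1 and 2, 7 and 147 without shNC replicates 1 and 2 and 80 without H3.1K9M replicate 1. Feeder markers averaged 3.67 and 4.34 in H3.1WT and 3.91 and 4.35 in shNC. By camera 12 lists differed between the controls, and none with an estimated correlation, where 4 had an unadjusted p under 0.05. Higher in H3.1WT were 2 of 11 primed genes (5 adjusted over the list alone; median 0.35, adjusted p = 1.24e-05) and 5 of 16 primitive streak genes (8 higher and 1 lower adjusted over the list alone; median 0.29, adjusted p = 0.00037). Krt8, singled out with Lef1 and Cdx2 after their values were seen, stood at 55.7 ± 1.94 FPKM in H3.1WT and 13.5 ± 0.938 in shNC (SD, n = 2), Lef1 at 11.4 ± 0.988 and 5.58 ± 0.62, and Cdx2 at 3.45 ± 0.917 and 0.155 ± 0.0947. Of 16 trophectoderm genes 4 were higher in H3.1WT, with a median of 0.11 (camera adjusted p = 0.0355). That adjusted p was 0.0675 without H3.1WT replicate 1, 0.194 without shNC replicate 2 and 0.0659 without H3.1K9M replicate 1. The interferon list was lower in H3.1WT, as given above, and the ATF4 and zinc finger lists were higher. In the share of tested genes whose 4 libraries did not overlap between groups, this comparison stood at 39.4%, H3.1K9M at 35.2% and H3.1K36M at 65.9% against H3.1WT, shSuv39h1 at 39.4% and shSuv39h2 at 50.8% against shNC, the mutants at 52.0% and the knockdowns at 58.7%, where chance gives 33.3%. That value assumes groups of equal spread, which these were not, and genes of a library can deviate together. Shares such as 35.2% or 39.4% therefore cannot be read as above chance.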

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

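The feeder marker covariate, leaving out chromosomes 11, 16, 19 and Y, and leaving out H3.1K9M replicate 1 in comparisons without that group were tests chosen after seeing the data, and the other alternatives were fixed before the data were examined. Single genes were run over the alternatives without array quality weights and the threshold on the fold change. The called genes chosen by the naming rule gave 2933 pairs of gene and setting. Of these, 2426 kept direction and threshold, 507 no longer passed and 0 reversed by limma's fits. Genes named for the largest fold changes had libraries that did not overlap between groups. Leaving out a library or changing the pseudocount could therefore not reverse them, and the 0 says little. The Suv39h2 decrease in shSuv39h2 kept its direction when each library was left out, at −1.15 to −1.07 on the log2 scale, and the Suv39h1 difference in shSuv39h1 lay at −0.67 to −0.50. For the counts and values that moved, the cause was not tested. The main fit gave every group the same spread, while the SD between libraries was 0.41 in H3.1K9M and 0.223 in H3.1K36M. Its p-values can thus be too small in comparisons with H3.1K9M and too large for H3.1K36M against H3.1WT. In a fit over the compared pair alone the latter gave 1786 genes in place of 634, although with fewer libraries.

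Counts of called genes are given first. With no filter on low values, H3.1K9M against H3.1WT gave 12 genes. A minimum of 5 FPKM, which tests fewer genes, gave 27 in H3.1K9M, 354 in H3.1K36M, 663 between the mutants and 29 between the controls. Array quality weights gave 1 gene in H3.1K9M, 2983 in H3.1K36M, 507 between the mutants, 860 in shSuv39h2 and 2103 between the knockdowns. The feeder marker covariate gave 25 in H3.1K9M, 1925 between the mutants, 2196 in shSuv39h2 and 180 between the controls. Fits over the 3 groups of an arm, with fewer libraries for the spread, gave 2 in H3.1K9M, 186 in H3.1K36M, 510 between the mutants, 3 in shSuv39h1, 866 in shSuv39h2 and 348 between the knockdowns. Fits over the compared pair of groups gave 3 in H3.1K9M, 1786 in H3.1K36M, 127 between the mutants, 1 in shSuv39h1, 145 in shSuv39h2 and 1 between the controls. Requiring a log2 change of at least 1 left 23, 109, 183, 6, 127, 75 and 17, in the order H3.1K9M, H3.1K36M, mutants, shSuv39h1, shSuv39h2, knockdowns and controls. A pseudocount of 0.1 gave 11 genes in shSuv39h1, and leaving out chromosomes 11, 16, 19 and Y gave 8 in shSuv39h1, 814 in shSuv39h2 and 367 between the knockdowns.

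The deviations of replicates correlated over 0.1 in 4 of 15 pairs of groups, with a range of −0.384 to 0.517. Replicate numbers thus marked no pairing common to all groups. Large correlations of both signs remain, so a batch that the numbers do not mark cannot be excluded. With a replicate block the counts in the same order were 39, 595, 1069, 10, 1323, 852 and 40.

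Leaving out 1 library, with the lone library assumed to vary like the other groups, gave 2 to 695 genes in H3.1K9M, 107 to 1185 in H3.1K36M, 267 to 1424 between the mutants, 0 to 58 in shSuv39h1, 360 to 1998 in shSuv39h2, 76 to 1438 between the knockdowns and 7 to 147 between the controls. The 0 was without shSuv39h1 replicate 1, where limma had 905 genes at an unadjusted p under 0.05. The correlation of the H3.1K9M and shSuv39h1 responses ranged from −0.22 to 0.0873 and reversed without H3.1K9M replicate 1. It was −0.264 with the feeder covariate. The H3.1K9M and shSuv39h2 correlation ranged from 0.235 to 0.336, with 0.204 under the covariate and 0.342 at a pseudocount of 0.1. The H3.1K9M and H3.1K36M correlation ranged from 0.057 to 0.559, and that of the knockdowns from 0.41 to 0.658.

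By camera, 18, 16, 14, 10, 14, 12 and 12 lists passed in the same order. With an estimated correlation 0, 0, 1, 0, 0, 0 and 0 passed, and camera's unadjusted p was under 0.05 for 5, 5, 8, 8, 7, 6 and 4 lists. Fry called 5 lists in H3.1K9M, 7 in H3.1K36M, 4 in shSuv39h1, 9 in shSuv39h2 and 5 between the controls. In shSuv39h2 a minimum of 5 FPKM gave 9 lists and quantile normalization 8, in H3.1K9M the covariate gave 8, and between the controls a minimum of 5 FPKM gave 7. The mismatch repair list in H3.1K9M reversed without H3.1K9M replicate 1, with adjusted p values of 7.27e-05 to 0.912 over the libraries left out. The feeder list in H3.1K36M reversed under the covariate built from its own genes (0.489). Between the controls the feeder list reversed without H3.1WT replicate 1, with adjusted p values of 2.95e-09 to 0.566 over the libraries left out. Array quality weights were run for counts of genes alone, and a count-based test was not run, since the files hold no read counts. Depth limits genes near 1 FPKM, which stood for 44.7 to 59.0 fragments at 2 kb.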

Other observations

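All tests below examine chromosomes and lists that were picked because they stood out in these data, so none of them was planned before the data were seen. The test of a uniform loss of the Y chromosome and those with the feeder marker covariate were also chosen after the results were seen. Between H3.1K36M and shSuv39h2, which share no control, 92 genes rose in the mutant and fell in the knockdown by limma's calls. Independent lists would share 19, although calls from the same fit, with the same estimate of each gene's spread, are not fully independent. The same pair of responses shared 26 genes that rose and 23 that fell, where 21.7 and 10.7 would be shared, and 29 genes fell in the mutant and rose in the knockdown, where 12.2 would. Across all tested genes, which are not independent replicates, their r was −0.0508. Of the 92 genes, 23 lie on chromosome X, 11 on chromosome 11 and 15 belong to the germline, 2-cell-like and X-linked lists. Rhox5 had log2 fold changes of 1.32 and −1.36, Fkbp6 1.40 and −2.19, Xlr5a 2.14 and −1.17, Rhox1 1.16 and −1.89, Tuba3a 1.20 and −1.23, Naaa 0.80 and −0.73 and Obox6 0.91 and −0.96. Arl14epl, Dazl, Fkbp6, H2bfm, Nlrp4c and Rhox13, singled out after their values were seen, also fell in H3.1K9M, at −1.14, −1.08, −0.95, −1.10, −0.73 and −0.995.

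The 62 tested germline, 2-cell-like and X-linked genes had medians of −0.51 in H3.1K9M, −0.72 in shSuv39h2 and 0.43 in H3.1K36M, −0.16 in shSuv39h1 and −0.02 between the control lines. The 26 germline genes alone did not rise as a list in H3.1K36M, with 14 higher and 12 lower (median 0.07, camera adjusted p = 0.443). The share of feeder cells was argued against as the whole cause in H3.1K9M and H3.1K36M, since at least 81.1% of each median remained with the feeder covariate. In shSuv39h2 the covariate could hardly act, as the feeder markers had a median of 0.06 against shNC. In 3 of 3 comparisons the median lay outside the central range of 10000 random lists matched on mean expression. Unrelated genes of like expression thus did not move as far. The test decides little beyond that, since the lists were picked because they moved and random genes do not share reads as near-identical copies do. In shSuv39h1, at a median of −0.16, 0 of 10000 random lists lay at or below the median as well. Drift between separately kept lines stays open, since the labels give no more than 1 line per group. Between the control lines the same genes had a median absolute log2 fold change of 0.235, which ignores direction and was not compared with genes of like expression. Their signed median there, −0.0217, lay within the central range of the random lists, −0.0607 to 0.0566. The control lines thus showed no joint shift of the 62 genes as a set, which does not exclude drift in another line. An effect of the mutants and the knockdown on these genes also stays open and was not tested apart from drift.

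The shifts of chromosomes 11 and 19 in shSuv39h2 and chromosome 16 in H3.1K36M were −0.277, 0.304 and 0.175, against at most 0.0519 on any other autosome. With the feeder covariate the chromosome 16 shift was 0.123, against at most 0.0515 on any other autosome, so the share of feeder cells does not account for it as a whole. The covariate could hardly act in shSuv39h2, where feeder markers had a median of 0.06. Against genes of like GC content and transcript length at least 89.8% of each shift remained, so these do not account for the shifts as a whole. Each chromosome was divided, in gene order, into 4 equal parts. All parts of these chromosomes moved in the chromosome's direction, the smallest by 0.135, while no part of another autosome moved by more than 0.0915. A change in chromosome copy number in part or all of the cells may therefore underlie them, and no DNA measurement was analysed here. No source says whether the lines were derived separately, so an effect of the knockdown or mutant on these chromosomes stays open and untested.

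Of 6 tested genes on chromosome Y 2 fell in H3.1K9M, 3 in shSuv39h1 and 5 in shSuv39h2. The Y-linked list holds 5 of them, without Uba1y, and did not pass with an estimated correlation (adjusted p = 0.139, 0.0792 and 0.0854). A uniform loss of the Y chromosome as the only cause would leave the same share of each gene, whereas in H3.1K9M Uba1y stood at 32.8% ± 2.98, Ddx3y at 67.5% ± 1.9, Eif2s3y at 75.8% ± 16.6 and Uty at 83.3% ± 8.15 of control (SD, n = 2). The ratio of the highest to the lowest share was 2.54 there, 1.97 in shSuv39h1 and 2.2 in shSuv39h2, which argues against uniform loss as the only cause. This rests mainly on Uba1y, since without it the ratios were 1.23, 1.4 and 1.58, and only the last exceeded the 1.5 set for the test. The share of feeder cells was argued against as the whole cause in H3.1K9M and shSuv39h1, since at least 69.8% of the list's median remained with the feeder covariate (−0.28 from −0.40 and −0.76 from −0.73). In shSuv39h2 the feeder markers had a median of 0.06 against shNC, so the covariate could hardly act, and the list's median of −1.13 with it decides nothing. Loss in some cells together with reads shared with X-linked homologues or RNA from feeders, and a direct effect on the Y chromosome, may each contribute and were not tested.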
